A study of Homo sapiens with 8 samples.

How the data were processed

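Polyadenylated RNA was sequenced from 8 libraries of human neural stem cells at day 12, 4 WT and 4 RGCC knockout. The labels disagree on the source: they name embryonic stem cells in the growth protocol, induced pluripotent cells in the source name, and RNA from single organoids in the extraction protocol. The cells are called neural stem cells here, after the name the authors gave their deposited table. The sample titles give H9 (WT) or KO (RGCC KO) and no cell type. The library kit named in the labels is not stated to mark strand, so a gene and an overlapping or antisense partner cannot be told apart.

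Per the submitters' processing notes, reads were handled with HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2, with the genome build hg38; the notes give no role or order. The authors deposited, per the file headers, a raw count and an FPKM value per gene and library, and their own log2 fold change, p-value and adjusted p-value. The authors also deposited a signal per gene and group, which from its values is a group mean of counts divided by size factors; it was not used here. In each library FPKM times gene length was proportional to the count, and the library sizes in the FPKM values were proportional to median-of-ratios size factors. IDs, positions and strands of all 58735 genes equalled GENCODE release 29. The authors' deposited values list 27 gene symbols that had been turned into dates; they were restored through the gene ID, after which all symbols equalled GENCODE. The authors' deposited table gave 3567 genes with an adjusted p below 0.05, 2021 higher and 1546 lower in knockout, and for RGCC a log2 fold change of -2.48 with an adjusted p of 1. Of the genes tested here, the authors' deposited table called 3335, and 3101 of these were also called here.

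Before the data were examined, the test was fixed as limma on log2(FPKM + 1), or edgeR if the table held raw counts instead. The table held both, a case the plan did not name, and edgeR was then taken as the main test. It was edgeR 4.0.16 (quasi-likelihood, TMM, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The test used counts of the 13472 genes with a mean FPKM of at least 1 over all 8 libraries. The limma fit became an alternative. CPM values are TMM-normalised over the tested genes, except for RGCC and the CHCHD2 bound, which use all reads. The standard error of a log2 fold change is its size over the root of the F statistic.

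The 33 gene lists were also fixed before the data were examined; 2 members were matched through an older symbol. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, beside an estimated correlation and fry. The fry test, which asks whether a list moves on balance and does not compare it with other genes, called 14 lists. Chromosomes were tested with camera at an estimated correlation. The genes named are RGCC; the 12 largest rises and 12 largest falls among protein-coding genes past the test with all 4 RGCC_KO libraries on one side of all 4 WT libraries; up to 4 members of each list with the smallest adjusted p among those past the test; and ACTB and GAPDH. Other list members named, and the genes without a read in a group, were chosen after their values were seen. Genes used for sex typing are not named, and some other genes that the rule takes are not reported here.

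GC content came from the longest GENCODE transcript of each gene and was known for 13465 of the tested genes. The trend on GC content and log2 gene length was fitted per library with natural splines of 5 degrees of freedom each and removed through offsets. Replicates were compared by a chi-square test of counts; no pair agreed within sampling noise (2.08 to 10.3 per degree of freedom), so each library counts once. Exact permutation tests over the 70 assignments of 4 against 4 were two-sided. Floors are 3 reads, and the ratio interval is an exact 95% one.

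The fit was tested on simulated counts with 200 changed genes among the 13472. It recovered 43.3%, 83.6% and 100% of changes of 0.25, 0.5 and 1 on the log2 scale and called 11 unchanged genes. With the GC and length trend of the real libraries added, it called 190 unchanged genes, and 10 once the trend was removed. The trend was added and removed with the same spline model, so this does not show that the model suits the real libraries. Alternatives were other pseudocounts, filters, scalings, tests (limma-voom, DESeq2 1.42.0, limma with and without a trend), the replicate number as a block, protein-coding genes only, and leaving out each library. Pseudocounts, quantile scaling and rescaled FPKM apply to the limma fit and were run there. Exact tests of library measures used SciPy 1.17.1.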

Results

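The data are RNA-seq gene counts from human neural stem cells grown as a flat (2D) culture and collected on day 12, with 4 wild-type (WT) libraries from H9, an established human embryonic stem cell line, and 4 libraries from RGCC knockout cells (RGCC_KO). RGCC (regulator of cell cycle) encodes a small protein that binds cyclin-dependent kinase 1. The deposited table gave a count and an FPKM value for each of 58735 genes in each library. Between 16246382 and 18258781 reads were counted per library, so that 1 read was worth 0.0548 to 0.0616 CPM, the count scaled by the library total. The labels do not say whether replicates were separate cultures or how many knockout clones were used, so p-values measure only the spread between these samples, which may be technical.

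The design has 1 comparison, RGCC knockout against WT, which asks how gene expression differs between them, and the targeted gene was read first. RGCC (ENSG00000102760, chromosome 13, 41457559 to 41470882, hg38) was close to the detection limit in every library. WT replicates 1 to 4 held 1, 3, 2 and 1 RGCC reads, which is 7 reads of 69472852, and the RGCC_KO libraries held 0, 0, 0 and 1, which is 1 read of 70238547. The ratio of RGCC_KO to WT was 0.141 with a 95% exact interval of 0.00314 to 1.10, which covers counting error only. On CPM the groups separated (0.0993 ± 0.0504 against 0.0141 ± 0.0282, SD, n = 4, exact two-sided permutation p = 0.0286), the smallest p that 4 against 4 allows. That order rests on library size alone, because RGCC_KO replicate 4 and WT replicates 1 and 4 each held 1 read. On unscaled reads the exact permutation p was 0.0857, and with median-of-ratios scaling it was 0.0571. RGCC level therefore could not check the labels at this depth.

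Of the 13472 genes with a mean FPKM of at least 1, 3631 differed between RGCC_KO and WT by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. In RGCC_KO 1747 of them were higher and 1884 lower. Most changes were small, with a median absolute log2 fold change of 0.257 and 88.8% of the changed genes below 0.5. The 60 changed genes with an absolute log2 fold change of at least 1 were mostly lower in RGCC_KO, 46 against 14. That number depended on the filter and scale, with 231 (188 lower, 43 higher) with no filter, 13 (11 and 2) with a mean FPKM of at least 5, 32 (27 and 5) among protein-coding genes, and 21 (17 and 4), 23 (17 and 6) and 5 (3 and 2) by limma on log2(FPKM + 1), on its quantile-normalized values and on log2(FPKM + 5). All 4 RGCC_KO libraries lay on one side of all 4 WT libraries for 3599 genes, 26.7% of those tested, and chance gives such a separation for 2.86%. The split between directions depended on scaling, since FPKM rescaled to a common sum and tested with limma gave 689 higher and 1712 lower, and limma on FPKM as deposited gave 1747 higher and 1260 lower. The housekeeping genes ACTB (log2 fold change 0.08, adjusted p = 0.172) and GAPDH (-0.08, adjusted p = 0.176) did not pass the edgeR test. Once each library's trend on GC content and gene length was removed, ACTB passed (log2 fold change 0.14, edgeR adjusted p = 0.0304) and GAPDH changed sign without passing (0.013, edgeR adjusted p = 0.861).

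Among protein-coding genes that passed the filter and the test with separated libraries, the deepest losses were in a few single genes. Genes below the filter, some with deeper falls, are left out of this ranking. CHCHD2 (chromosome 7, 56101569 to 56106576), which encodes a mitochondrial intermembrane space protein, had 3277 reads over the 4 WT libraries and 0 in all 4 RGCC_KO libraries, at least 1104-fold lower against a floor of 3 reads over the group. CCDC152 (chromosome 5, 42756801 to 42802360) fell by 4.73 on the log2 scale (SE 0.186, edgeR adjusted p = 8.19e-12), from 10.6 ± 0.588 to 0.392 ± 0.0817 CPM (SD, n = 4). PCDHB5, a clustered protocadherin gene on chromosome 5, fell by 2.03 (SE 0.0862, edgeR adjusted p = 2.41e-11), from 35.4 ± 0.92 to 8.67 ± 1.19 CPM. PEG3, an imprinted zinc finger gene on chromosome 19, fell by 1.66 (SE 0.076, edgeR adjusted p = 7.13e-11), from 80.0 ± 9.37 to 25.3 ± 0.949 CPM. C4orf47, the lactate exporter gene SLC16A3, SLITRK1, TBX10, ZNF558, PDE12, TMEM88B and ZNF585A fell by between 1.33 and 1.12. The call for TMEM88B ended without WT replicate 1 (edgeR adjusted p = 0.0925) and once the GC trend was removed (0.104), with 0.248 in the 4 libraries of least steep GC trend.

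Increases were smaller. The metallothionein gene MT1E rose by 1.45 (SE 0.187, edgeR adjusted p = 4.46e-05), from 1.67 ± 0.211 to 4.57 ± 0.724 CPM (SD, n = 4). ESD, the esterase D gene on chromosome 13, rose by 1.25 (SE 0.0484, edgeR adjusted p = 8.19e-12), from 55.2 ± 1.83 to 131.3 ± 5.47 CPM. PSMD5, a proteasome assembly factor gene, rose by 1.10, TRIM22 by 1.10 and LUM, which encodes the matrix proteoglycan lumican, by 1.02. PKIB, NMRK2, CDH6, RAB33A, ZNF736, CLMP and ZNF385B rose by 0.97 to 0.77. Exons of 10 of these 24 genes overlap those of another annotated gene, so the counts of CCDC152, PCDHB5, PEG3, SLC16A3, SLITRK1, ZNF558, ZNF585A, TRIM22, PKIB and CDH6 are uncertain. The same holds for PFKFB4, PGK1, HMGCS1, CANX, HSP90B1, TAGLN, ACTA2, KRT8, KRT18, KIF23, PHLDA3, TP53I3 and GAPDH.

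**Figure D1:**
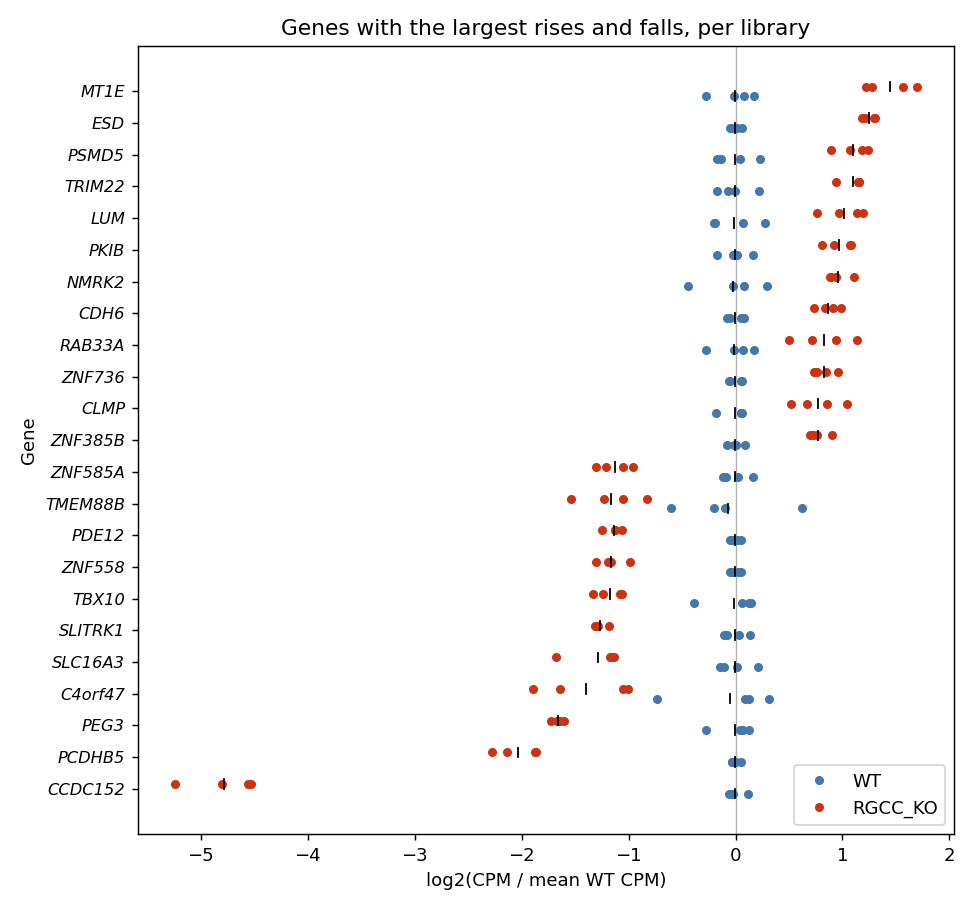
Each point is the log2 ratio of a library's CPM to the mean WT CPM (horizontal axis) for the genes with the largest rises and falls (vertical axis), WT in blue and RGCC_KO in red, with a black bar at the mean of each group of 4 libraries. CHCHD2 is left out because its RGCC_KO count is 0; CCDC152 fell by 4.73 on the log2 scale and MT1E rose by 1.45.

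Genes of hypoxia and glycolysis were lower in RGCC_KO. Of 18 measured members, 16 fell, 0 rose and 2 did not pass; adjusted over the list alone 16 were lower and 1, SLC2A3, higher. The list's median log2 fold change was -0.43, and in 14 members all RGCC_KO libraries lay below all WT libraries. PFKFB4, a regulator of glycolytic flux, fell by 1.01 (SE 0.0658, edgeR adjusted p = 1.3e-08). LDHA, the lactate dehydrogenase A gene, fell by 0.71 (SE 0.0557), BNIP3, a mitophagy receptor gene, by 0.63 (SE 0.0555) and PGK1, a glycolytic kinase gene, by 0.63 (SE 0.0467). The glucose transporter genes parted, with SLC2A1 falling by 0.35 and SLC2A3 at 0.10 (edgeR adjusted p = 0.11). The list passed camera with a preset correlation (adjusted p = 7.07e-13) but not with an estimated correlation (adjusted p = 0.196; range over the settings run 4.81e-21 to 0.196).

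Cholesterol synthesis genes were higher in RGCC_KO, with 11 of 15 past the test, 4 not past it and a median log2 fold change of 0.30; adjusted over the list alone 11 were higher and 1, MVD, lower. INSIG1, a sterol-regulated feedback gene, rose by 0.59 (SE 0.0515, edgeR adjusted p = 6.65e-07), MSMO1 by 0.46 and HMGCS1 by 0.33. This was the only list called by camera with both the preset (adjusted p = 1.8e-07) and the estimated correlation (adjusted p = 0.0245; range over the settings run 5.24e-14 to 0.0245). Of 19 measured genes of the unfolded protein and integrated stress response, 9 rose, 1 fell (SESN2) and 9 did not pass, with a median of 0.17; adjusted over the list alone 11 were higher and 2 lower. The endoplasmic reticulum chaperone genes HSPA5 (0.38), CANX (0.36) and HSP90B1 (0.22) were among those that rose, as was PSAT1 (0.25), a serine synthesis gene. The list's camera adjusted p was 0.00204, and the adjusted p = 0.196 with an estimated correlation (range over the settings run 3.12e-06 to 0.196).

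Both groups expressed genes of the neural stem cell list, with SOX2 at 714 ± 23.5 and 658 ± 31.6 CPM in WT and RGCC_KO (SD, n = 4). The log2 fold change of SOX2 was -0.12 (edgeR adjusted p = 0.0619). This does not settle the cell type, because DNMT3B of the pluripotency list stood at 274 ± 6.08 and 319 ± 9.8 CPM. Of 20 measured neural stem cell and radial glia markers, 8 fell, 3 rose and 9 did not pass; adjusted over the list alone 9 were lower and 5 higher. HES5, a Notch effector, fell by 0.79 (SE 0.0664, edgeR adjusted p = 3.79e-07), NES, the nestin gene, by 0.48 and NOTCH1 by 0.33, while VIM rose by 0.23. The list as a whole, with a median of -0.12, missed the threshold (camera adjusted p = 0.0545; adjusted p = 0.25 with an estimated correlation) and passed with the GC trend removed (adjusted p = 0.0493; adjusted p = 0.27 with an estimated correlation). Among 12 anterior and dorsal forebrain patterning genes 6 fell, 0 rose and 6 did not pass, with a median of -0.20 and the same counts adjusted over the list alone. DMRTA2 fell by 0.88 (SE 0.119) and RAX by 0.43 (SE 0.0486). The camera call on this list (adjusted p = 0.0326; adjusted p = 0.196 with an estimated correlation; range over the settings run 0.00679 to 0.233) ended without WT replicate 1 (0.0578), RGCC_KO replicate 3 (0.0511) or RGCC_KO replicate 4 (0.0544), and once the GC trend was removed (0.233), which left 4 lower, 1 higher and a median of -0.13. In the 4 libraries of least steep GC trend the median was -0.07.

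Of 16 Notch pathway genes 8 fell, 2 rose and 6 did not pass, with a median of -0.16; adjusted over the list alone 9 were lower and 2 higher. LFNG, which modifies Notch receptors, fell by 0.58 (SE 0.0536) and HEY1 rose by 0.60. The camera adjusted p was 0.0239, with an adjusted p = 0.225 with an estimated correlation and 0.547 with the GC trend removed (range over the settings run 0.00319 to 0.547). With that trend removed the Notch median was -0.02, with 5 lower and 2 higher. Among 9 proneural and intermediate progenitor genes 3 fell (NHLH1 by 0.56, BTG2 by 0.28 and DLL3 by 0.17; the same 3 adjusted over the list alone), 0 rose and the median was -0.27. The call for DLL3 ended without any one library except RGCC_KO replicate 3 (edgeR adjusted p = 0.0505 to 0.107) and with the GC trend removed (0.908). The list's camera adjusted p of 0.0313 became an adjusted p = 0.25 with an estimated correlation, 0.0604 without WT replicate 1 and 0.5 with the GC trend removed (range over the settings run 0.00369 to 0.5). The proneural median was nearer 0 with the GC trend removed (-0.09), with limma on log2(FPKM + 1) (-0.14), with a mean FPKM of at least 5 (-0.07) and without WT replicate 1 (-0.15), WT replicate 3 (-0.17) or RGCC_KO replicate 1 (-0.155). Of 7 pluripotency genes 3 rose (DNMT3B by 0.22, TERF1 by 0.22 and DPPA4 by 0.18; the same 3 adjusted over the list alone), with a median of 0.14 and a camera adjusted p of 0.0326, an adjusted p = 0.196 with an estimated correlation, 0.0572 without RGCC_KO replicate 3 and 0.104 with the GC trend removed (range over the settings run 0.0119 to 0.196). Removing the GC trend left 2 of the 7 pluripotency genes higher and a median of 0.02, and the call for DPPA4 ended (edgeR adjusted p = 0.0567). DPPA4 also lost its call with rescaled FPKM (limma adjusted p = 0.0825) and in the 4 libraries of least steep GC trend (edgeR adjusted p = 0.265). So did TERF1, with rescaled FPKM (limma adjusted p = 0.0806) and in those 4 libraries (0.136, edgeR adjusted p = 0.195). Neuronal differentiation genes went both ways, with 3 of 12 lower and 2 higher by either adjustment, all-gene or adjusted over the list alone (camera adjusted p = 0.878), and 2 each way with a median of -0.04, from 0.05, with the GC trend removed.

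Cell cycle genes moved little. Of 24 G2/M and mitosis genes 10 rose, 1 fell (BIRC5) and 13 did not pass, by either adjustment (all-gene or adjusted over the list alone). TTK rose by 0.34, KIF23 by 0.30, BUB1 by 0.26 and CDK1 by 0.25. With the GC trend removed 5 were higher and 1 lower with a median of 0.06, and CDK1 (edgeR adjusted p = 0.075), TOP2A (0.149), KIF11 (0.473), BUB1B (0.507) and NDC80 (0.137) no longer passed. The list's median was 0.09 and its camera adjusted p 0.00025, with an adjusted p = 0.337 with an estimated correlation (range over the settings run 1.5e-08 to 0.337). For G1/S and DNA replication 3 of 24 genes rose and 2 fell, for centrosome and spindle orientation 5 of 26 rose and 3 fell, and for tubulins and microtubule-associated proteins 4 of 20 rose and 2 fell; adjusted over the list alone the counts were the same, and camera called none of these lists (adjusted p = 0.527, 0.511 and 0.878). The balance turned in each once the GC trend was removed, to 3 higher and 4 lower for G1/S and DNA replication, 2 and 4 for centrosome and spindle orientation, and 3 and 4 for tubulins, and camera's direction for the centrosome list turned from up to down (adjusted p = 0.948). Of 19 p53 targets and CDK inhibitors 8 fell, 2 rose and 9 did not pass by either adjustment (all-gene or adjusted over the list alone). TP53I3 fell by 0.68 and PHLDA3 by 0.56, CCNG1 rose by 0.28, and CDKN1A stood at -0.09 (edgeR adjusted p = 0.182). The median was -0.09. Camera's adjusted p of 0.0326 for this list became an adjusted p = 0.271 with an estimated correlation, 0.0574 without WT replicate 1 and 0.0511 without RGCC_KO replicate 3 (range over the settings run 0.0123 to 0.271).

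Markers of other cell types were measured where they passed the expression filter. Of 6 measured surface ectoderm and epithelial markers 5 rose, KRT18 by 0.36, EPCAM by 0.63, KRT8 by 0.19 and GRHL3 by 0.23 among them; adjusted over the list alone all 6 were higher (median 0.21, camera adjusted p = 0.000386; adjusted p = 0.196 with an estimated correlation; range over the settings run 2.32e-06 to 0.196). KRT8 and KRT18 share exon positions. Mesoderm and mesenchyme markers went both ways, with LUM, COL1A1 and PDGFRB higher and TAGLN (-0.61) and ACTA2 (-0.59) lower of 6 measured (3 and 2 adjusted over the list alone; camera adjusted p = 0.699). Fewer than 5 members were measured for glial, neural crest, endoderm, endothelial and blood, roof plate and choroid plexus, and ventral patterning markers, so these lists were not tested. TIE1 rose among 2 endothelial and blood markers and BMP4 among 3 roof plate and choroid plexus markers, while 0 of 4 neural crest, 0 of 1 endoderm and 0 of 1 ventral patterning genes passed; adjusted over the list alone 2 endothelial and blood markers were higher and the other counts stayed. Removing the GC trend made 1 neural crest gene pass as higher, NGFR (log2 fold change 0.21, edgeR adjusted p = 0.0487). The call for BMP4 ended without WT replicates 1 (edgeR adjusted p = 0.0813) or 2 (0.0688) or RGCC_KO replicates 2 (0.0549) or 4 (0.0625). Of 6 midbrain, hindbrain and caudal patterning genes FGF8 fell by 0.39 (1 also adjusted over the list alone; camera adjusted p = 0.882). Once the GC trend was removed FGF8 fell by 0.18, IRX3 rose by 0.37 (edgeR adjusted p = 0.0156), the list's median went from 0.03 to 0.14 and camera's direction turned from down to up (adjusted p = 0.459). The list's mean level per library then had an exact permutation p of 0.0286, against 0.886 before. That is the smallest p that 4 against 4 allows, and it becomes 0.0593 after Benjamini-Hochberg adjustment over the 27 lists.

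Immediate early and heat shock genes were lower, with 8 of 12 falling and HSPH1 rising; adjusted over the list alone 10 were lower and 1 higher. EGR1 fell by 0.64, JUN by 0.49 and HSPA1A by 0.57. HSPA1A is nearly identical to HSPA1B, so its count is uncertain. In the 4 libraries of least steep GC trend the calls for EGR1 (-0.56, edgeR adjusted p = 0.0663) and JUN (-0.277, edgeR adjusted p = 0.0854) ended. Both passed with the GC trend removed in all 8 libraries (EGR1 -0.57, edgeR adjusted p = 0.00351, and JUN -0.42, edgeR adjusted p = 0.00206). The median was -0.36 and the camera adjusted p 0.00153, with an adjusted p = 0.196 with an estimated correlation (range over the settings run 5.62e-06 to 0.196). Of the 13 mitochondrially encoded protein genes 3 rose (4 adjusted over the list alone), MT-CYB by 0.50, MT-ND2 by 0.42 and MT-ND3 by 0.27, but the groups overlapped on each of these genes (list median 0.27, camera adjusted p = 0.00729; adjusted p = 0.652 with an estimated correlation; range over the settings run 1.35e-06 to 0.706). The call for MT-CYB ended in 9 of 24 settings, without RGCC_KO replicate 2 (edgeR adjusted p = 0.0626), with DESeq2 (0.0743) and with robust quasi-likelihood (0.154) among them, that for MT-ND2 in 8 of 24 (DESeq2 adjusted p = 0.0536, robust quasi-likelihood 0.128) and that for MT-ND3 in 3 of 24 (limma adjusted p = 0.0508 to 0.319). The median of the mitochondrially encoded protein genes was 0.42, 0.16, 0.41 and 0.14 without WT replicate 2, WT replicate 4, RGCC_KO replicate 1 and RGCC_KO replicate 2, and 0.03 on quantile-normalized values. Camera did not call nuclear-encoded oxidative phosphorylation genes (17 of 79 lower and 5 higher, 3 of the 79 processed pseudogenes, adjusted p = 0.15), cytosolic ribosomal proteins (11 of 78 higher and 8 lower, 0.882), interferon-induced genes (1 of 7 higher and 1 lower, 0.882), imprinted genes (3 of 11 higher and 3 lower, 0.91), clustered beta protocadherins (3 of 11 lower and 1 higher, 0.0544), Wnt pathway genes (3 of 11 higher and 2 lower, 0.992), TGF-beta and BMP pathway genes (3 of 15 higher and 2 lower, 0.511) or extracellular matrix and integrin genes (4 of 20 higher and 6 lower, 0.878). Adjusted over the list alone these counts were unchanged, except 4 and 4 for imprinted genes and 5 higher for extracellular matrix and integrins. With the GC trend removed the clustered beta protocadherins passed camera (adjusted p = 0.0264; adjusted p = 0.394 with an estimated correlation), and camera's direction turned from down to up for Wnt pathway genes (0.572) and interferon-induced genes (0.505). The balance of called members turned to 7 higher and 4 lower for extracellular matrix and integrin genes and to 9 higher and 10 lower for cytosolic ribosomal proteins. Median, mean and camera direction differed in sign for neuronal, caudal patterning, tubulin, extracellular matrix, imprinted and ribosomal protein genes.

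**Figure D2:**
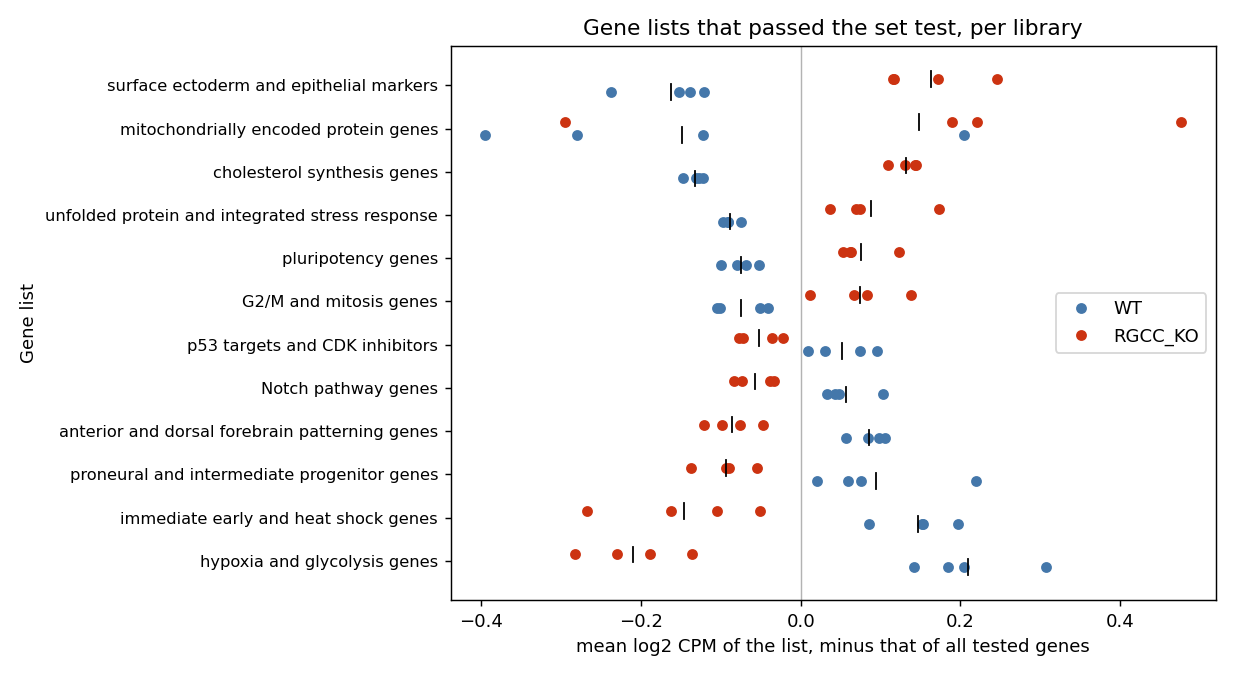
Each point is a library's mean log2 CPM over a list minus that over all tested genes, centred on the 8 libraries (horizontal axis), for the 12 lists past camera with a preset correlation (vertical axis); WT is blue, RGCC_KO red, and black bars are means of 4 libraries. The groups do not overlap for any list drawn except mitochondrially encoded protein genes, whose exact permutation p was 0.229.

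In all, 12 of the 27 lists with at least 5 measured members passed camera with the preset correlation and 1 with an estimated correlation. On log2(FPKM + 5), which shrinks the changes of genes of low FPKM, the medians were -0.22 for hypoxia and glycolysis, -0.14 for immediate early and heat shock, -0.08 for Notch and proneural, -0.115 for forebrain patterning and 0.11 for unfolded protein response genes. Other medians that moved by over 1.5 times included 0.32 for surface ectoderm markers with no filter, -0.22 for immediate early and heat shock genes on quantile-normalized values, and 0.09 and 0.05 for pluripotency and G2/M genes with rescaled FPKM. An exact two-sided permutation test of each list's mean level per library, chosen after the data were seen, gave p = 0.0286 for 11 of these 12 lists. That is the smallest value possible, and it becomes 0.0593 after Benjamini-Hochberg adjustment over the 27 lists. With the GC trend removed 9 of the 12 had that p, and the exact permutation p was 0.2 for proneural, 0.371 for Notch and 0.257 for mitochondrially encoded protein genes.

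The libraries of the groups also differed in how expression followed GC content. The log2 CPM of each gene was first centred on its mean over the 8 libraries. Across genes, the centred values correlated with GC content at 0.33, 0.412, 0.096 and 0.141 in WT replicates 1 to 4. In RGCC_KO replicates 1 to 4 the correlations were -0.091, -0.353, -0.062 and -0.421 (exact permutation p = 0.0286, and 0.0667 adjusted over 7 library measures). Centring pushes the groups to opposite signs, so these values compare libraries and do not give the trend of expression itself within a group. The log2 fold change fell with GC content across genes (Spearman -0.433; genes are not independent replicates), from a median of 0.12 in the 1348 genes of lowest GC content to -0.19 in the 1347 of highest. After each library's trend on GC content and gene length was removed, 2896 genes passed, 2079 of them called before in the same direction. With the trend removed in all 8 libraries, 11 of the 123 named genes lost their call. With only the 4 libraries of least steep GC trend (WT replicates 3 and 4, RGCC_KO replicates 1 and 3), 1124 genes passed, and 31 of the 123 lost their call. Fewer libraries alone can also end calls, so this setting does not measure the part of the GC trend. Among genes named above that still passed with the trend removed, log2 fold changes were smaller by over 1.5 times for NOTCH1 (-0.21), TTK (0.22), BUB1 (0.16), KIF23 (0.20), CCNG1 (0.16), HSP90B1 (0.11), SESN2 (-0.14), HMGCS1 (0.22) and HSPH1 (0.15). RGCC_KO libraries also had fewer genes with a read, 25485 ± 442 against 26131 ± 253 (SD, n = 4, exact permutation p = 0.0286; 0.0667 adjusted). The correlation of the centred values with gene length separated the groups too, at 0.0592 ± 0.0422 in RGCC_KO and -0.0592 ± 0.0715 in WT (SD, n = 4, exact permutation p = 0.0286, and 0.0667 adjusted).

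**Figure D3:**
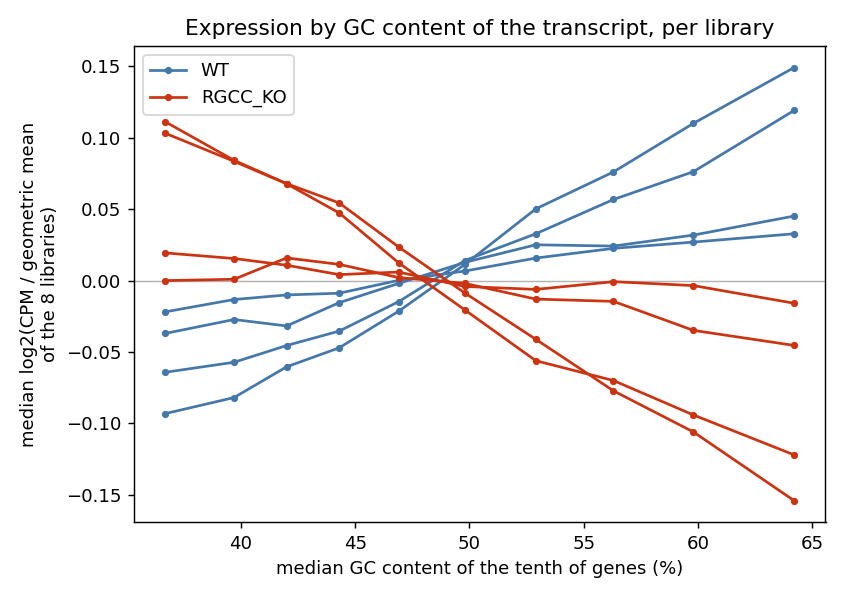
Each line is a library, WT in blue and RGCC_KO in red; the horizontal axis is the median GC content in percent of 10 equal bins of the tested genes and the vertical axis the median log2 ratio of CPM to the geometric mean of the 8 libraries. In the bin of highest GC content the WT libraries lie above 0 and the RGCC_KO libraries below it.

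Whether whole chromosomes stood apart depended on the correlation used in camera. Camera with an estimated correlation called 0 of 23 chromosomes (autosomes and X; lowest adjusted p 0.311; 1 at an unadjusted p below 0.05), and 7 with the preset correlation. Chromosome medians lay between -0.11 for chromosome 19 and 0.06 for chromosomes 4 and 13, and with the GC trend removed camera with an estimated correlation gave a lowest adjusted p of 0.591.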

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

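Of 259 groups of 4 values checked for a library far from the others, 12 stood out, and chance gives about 13 (1 in 20). The gap to the nearest library, as a share of the group's range, was 0.949 for TRIM22 in RGCC_KO (replicate 1 at 18.6 CPM, the others 21.4 to 21.6), 0.961 for CLMP in WT (replicate 4 at 6.67, the others 7.84 to 7.89) and 0.907 for SLC16A3 in RGCC_KO (replicate 4 at 22.8, the others 32.2 to 33.2). It was 0.848 for ZBTB16 in WT (replicate 4 at 41.2), 0.884 for TERF1 in RGCC_KO (replicate 2 at 78.2), 0.952 for RAX in WT (replicate 3 at 85.7) and 0.924 for CKAP5 in WT (replicate 2 at 608). For TGFBI in WT it was 0.921 (replicate 4 at 20.6), for PGK1 in RGCC_KO 0.836 (replicate 4 at 576), for PCDHB10 in RGCC_KO 0.884 (replicate 3 at 20.8) and for COX6A1 in WT 0.907 (replicate 1 at 30.8). The correlation of centred expression with gene length was 0.122 in RGCC_KO replicate 4 against 0.03 to 0.043 in the other RGCC_KO libraries, a share of 0.859.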

How the results depend on the processing

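The GC and length correction, the 4 libraries of least steep GC trend, DESeq2, and unscaled or TMM-scaled RGCC reads were chosen after seeing the data. The limma fit on log2(FPKM + 1), fixed beforehand, gave 3007 changed genes, 1747 higher and 1260 lower in RGCC_KO. The count of changed genes stayed within 1.5 times of 3631 except with rescaled FPKM (2401, with 689 higher), with the 4 libraries of least steep GC trend (1124, with 579 higher and 545 lower; fewer samples) and with a log2 fold change of at least 1 required (60). Genes lower in RGCC_KO numbered 1255 with a pseudocount of 5 and 1208 in limma without trend; the cause was not tested. Leaving out a library gave 2539 to 3828 changed genes. DESeq2 gave 3573. An estimated correlation left 1 list, and the preset correlation called 7 chromosomes. With the GC trend removed GAPDH changed sign, to 0.013, not past the test before or after. The log2 ratio of RGCC expression, -2.82 on CPM, lost its exact p of 0.0286 on unscaled reads (-2.81, exact p = 0.0857) and with median-of-ratios scaling (-2.78, exact p = 0.0571), because libraries with 1 read each then tie or change order. Without a library RGCC expression ranged from -3.01 to -2.40, where 3 against 4 cannot go below 0.0571; without RGCC_KO replicate 4 no ratio exists. Of 123 named genes 79 kept their call in each setting run, as did 21 of the 24 largest rises and falls. Changes of 0.25 on the log2 scale were recovered in 43.3% of simulated cases. The simulation held 200 changed genes, far fewer than the 3631 called here, so its Benjamini-Hochberg cutoff was stricter. That share therefore does not carry over to these data, and how many such changes go uncalled is not known. With the replicate number as a block 3965 genes passed and no named gene lost its call. Same-numbered samples correlated at 0.17, 0.027, -0.023 and 0.135, and not every sample correlated best with its own number. On the second component, with 14% of the variance, replicates 1 and 2 of both groups lay above 0. Replicates 3 and 4 lay below it, RGCC_KO replicate 3 only just (-0.271). Whether the numbers pair or group the samples stays open.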

Other observations

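The tests of the batch, culture and RGCC explanations and of SELENOP, the GC and length correction, the spread between libraries, and the search for genes without a read were chosen only after the results were seen. Besides CHCHD2, 3 genes had 0 reads in all RGCC_KO libraries and at least 10 in each WT library. They were PLSCR1, a phospholipid scramblase gene (409 WT reads, at least 138-fold lower in RGCC_KO), the zinc finger gene ZNF229 (351 reads, at least 118-fold lower) and CAT, the catalase gene (50 reads, at least 16.9-fold lower). No gene showed the opposite pattern under the same rule. PLSCR1, ZNF229 and CAT lay below the expression filter over all 8 libraries, with WT means of 1.33, 0.898 and 0.197 FPKM, and ZNF229 overlaps another annotated gene.

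Among 12 transcription factor families of the table, C2H2 zinc finger genes did not pass camera as fitted (adjusted p = 0.19) and were lower in RGCC_KO once the GC and length trend was removed. A hypothesis was that these genes move with their GC content. Their median over 466 genes was -0.05 before and -0.0984 after the GC and length trend was removed, with 82 members lower and 10 higher. The median over all tested genes was then -0.0261. These values argue against the hypothesis only as far as the spline model suits these genes, which was not tested. Of the 12 families, 2 passed camera after the correction. They were C2H2 (adjusted p = 0.000863; adjusted p = 0.333 with an estimated correlation) and ZBTB, whose median was -0.0954 (adjusted p = 0.0318; adjusted p = 0.213 with an estimated correlation).

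A first pattern is the large number of small changes. Of the 35 splits of the 8 libraries, 1, the real one, gave as many as 3631 genes, and the highest other gave 3. This argues against random spread between these libraries as the source of the changes, though ranking first is the smallest share 35 splits allow. Every other split mixes the groups, so any difference between WT and RGCC_KO, whatever its cause, would also put the real split first. The GC and length trend as the whole cause is argued against by the 2896 genes that passed without it, of which 2079 were among the 3631 in the same direction; the calls that ended may follow the trend. It stays open whether each group was grown, collected or prepared as its own batch. The component that separates the groups held 37.6% of the variance, and no label crosses group with batch, so batch and knockout cannot be told apart. The number of knockout clones is not given, so a difference between cell lines or clones cannot be told apart from either.

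A second pattern is the fall of CHCHD2, CCDC152, PCDHB5 and PEG3. Loss of a chromosome segment of this scale is argued against by the other genes within 1 Mb, whose lowest median over the 4 loci was -0.0844; a loss of the gene alone was not tested. Exons of 3 of the 4 genes overlap another gene, but CHCHD2 has no such overlap and SELENOP, which overlaps CCDC152, stood at 0.026 (edgeR adjusted p = 0.92), so shared reads do not account for those losses; for PCDHB5 and PEG3 the partners had at most 1 read and the question stays open. Whether the losses follow from the loss of RGCC cannot be told apart from a difference between cell lines or clones, since the 4 WT libraries held 7 RGCC reads and the number of knockout clones is not given.

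The third pattern is the lower hypoxia and glycolysis list. Its median was -0.43 before and -0.404 after the GC and length trend was removed, and it still passed camera with the preset correlation (adjusted p = 1.19e-15; adjusted p = 0.161 with an estimated correlation), which argues against that trend as the whole cause. In 14 of 18 members all RGCC_KO libraries lay below all WT libraries. Denser, less oxygenated or longer fed WT cultures could give the same fall, and no label records density, feeding or oxygen. Such a culture difference cannot be told apart from an effect of the knockout or from a difference between cell lines or clones.

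For the count of changed lists, 1 of 35 splits, the real one, gave as many as 12 by camera with the preset correlation, but the highest other split gave 11 and the median of the others was 4.5. Ranking first gives the smallest share that 35 splits allow, whatever the margin, and here the margin was 1 list. Chance is therefore not excluded by this count, for the lists together or for single lists. For chromosomes the real split gave 0 and the highest other 0, so 35 of 35 splits gave as many; with a real count of 0 this comparison decides nothing.

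A hypothesis that editing at the RGCC locus altered its neighbours was tested on the 39 genes within 5 Mb. Their median after the GC and length correction was -0.0045, at the 73.9 percentile of 10000 random sets of the same size. That is inside the middle 95% of random sets, the bound set before the test, so a shift of these genes together was not seen. A median near 0 cannot speak of genes that go both ways, and 4 of the 39 were called higher and 2 lower. This is a smaller share than over all 13472 tested genes, of which 3631 passed as fitted and 2896 with the trend removed. An effect on single neighbours stays open. A hypothesis that loss of CHCHD2 goes with lower nuclear oxidative phosphorylation transcripts was tested on 79 genes of that list. The median after correction was -0.0664 (SE 0.0127 over resampled genes), above the bound of -0.1 set before the test. The list's mean difference per library was -0.0458 (SE 0.0342 over libraries, n = 4, exact permutation p = 0.2). The bound of -0.1 lies within 2 of these SE of this mean, so a fall of that size in the mean stays open. The SE of the median covers the spread between genes only. The camera adjusted p was 0.0998, and 15 members were lower and 4 higher.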
